A study of Mus musculus with 8 samples.

How the data were processed

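Bulk RNA sequencing of mouse neutrophils was analysed, with 8 libraries in 2 groups: 3 libraries carry the treatment label aOX40 and 5 carry the label IgG. The group and the replicate number of each library came from the submitters' sample titles, and each column of the table was matched to its library by the sample name in the labels. The labels call the cells neutrophils and link them to B16 tumors, but they do not state how the cells were isolated. They also do not state whether each library came from a separate animal, so the p-values measure the spread between these libraries, which may in part be technical.

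The deposited table holds estimated counts per gene symbol, 18187 symbols in all, and its values were not scaled between libraries. Per the submitters' processing notes, the reads were handled with STAR 2.6.0, Subread and featureCounts 1.5.1 and the genome build was mm10; the settings and the annotation are not given in the sources used here. Of the deposited values, 63.4% were whole numbers within 0.01, and the rest carried fractions, so that reads appear to have been divided between genes at a step that is not given in the sources used here. The 32 largest values are printed in the table with 3 significant digits. The lowest row total in the table was 10 counts over the 8 libraries, and every row names a gene. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands may not be told apart.

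The estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, libraries were scaled with TMM factors, and the groups were compared with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with group as the only term in the model. The p-values were adjusted by the Benjamini-Hochberg method over the 13278 genes tested, and the threshold was an adjusted p of 0.05. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM, as given by the cpm function of edgeR with the TMM factors. Principal components used log2 CPM with a prior count of 2.

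For gene groups, 31 lists were fixed before the data were examined: 16 cell state lists, 12 lists of cell type markers and 3 lists of transcripts that follow RNA quality or tissue handling. The 26 lists with at least 5 members past the filter were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Group differences of single values, such as a list's mean log2 CPM or a library total, were tested with an exact two-sided permutation test over the 56 splits of the 8 libraries, whose smallest possible p is 0.0357.

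The genes named were set by a rule written before the data were examined. It took 13 focus genes whatever their values, the 8 higher and the 8 lower genes with the largest log2 fold change, and up to 4 members with the smallest adjusted p of each list described. The genes with the largest changes had to pass the threshold, reach a mean of 10 CPM in the higher group and have no overlap between the groups, and gene models with a number in place of a name were left out. The focus genes Tnfsf4, Ifng and Cd3e were not analysed here, and not every gene that the rule took is described.

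Positions came from GENCODE release M21 on GRCm38, the assembly also called mm10, by symbol; 17639 of the 18187 symbols were placed. Longest transcripts of the named genes were searched against all transcripts with BLAST+ 2.17.0, and a match of at least 95% identity over at least 50% of the transcript counted as a near copy. Of 68 named genes, 16 overlapped another gene of the table, and not all of these overlaps are mentioned below.

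The alternatives fixed before the data were examined were other scaling factors, other filters, DESeq2 1.42.0, limma voom with and without quality weights, 2 other settings of edgeR, each library left out in turn, and the replicate number as a block. Corrections for transcript length and GC content, and a restriction to genes with at least 10 counts in all 8 libraries, were added after the data were seen, and so was fry in the settings of edgeR. The procedure was tested on simulated data made from the real means and library sizes of the 13278 genes, with 200 genes changed. The changed genes were drawn only from those with a mean of at least 10 CPM, so the recovery rates do not cover genes at lower levels. It recovered 16% of genes changed 2-fold, 94% of those changed 4-fold, 98% of those changed 8-fold and 100% of those changed 16-fold, and 23 unchanged genes were called, which was 13.0% of the calls. With no gene changed it called 0 genes. Intervals on counts were not used, because reads without molecular identifiers are not independent molecules.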

Results

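The study measured gene expression in neutrophils from mice with B16 tumors, a mouse melanoma line, after treatment with aOX40 or with IgG. OX40 is the product of Tnfrsf4, a costimulatory receptor best known on activated T cells. The series title places the data in a study of whether T cell immunotherapy activates neutrophils, and the design implies 1 comparison: aOX40 against IgG. There were 3 aOX40 libraries (replicates 1 to 3) and 5 IgG libraries (replicates 2 to 6). The libraries held between 52.7 and 73.5 M counts (M, mega). The aOX40 libraries were deeper, with 71.1 ± 2.06 M counts (SD, n = 3) against 58.9 ± 5.02 M (SD, n = 5) in IgG, and held more genes with at least 10 counts, 13013 ± 313 against 11960 ± 476. Both differences had an exact two-sided permutation p of 0.0357, the smallest that 3 against 5 libraries allow, so depth and group went together in this series. The ferritin heavy chain gene Fth1 alone took between 4.27% and 7.88% of the counts of a library.

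The first principal component held 25.4% of the variance of log2 CPM and separated the groups without overlap (exact two-sided permutation p = 0.0357). Libraries correlated at 0.871 to 0.906 within aOX40, at 0.831 to 0.863 within IgG and at 0.807 to 0.856 between groups. IgG replicates 2 and 6 lay at opposite ends of the second component.

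**Figure D1:**
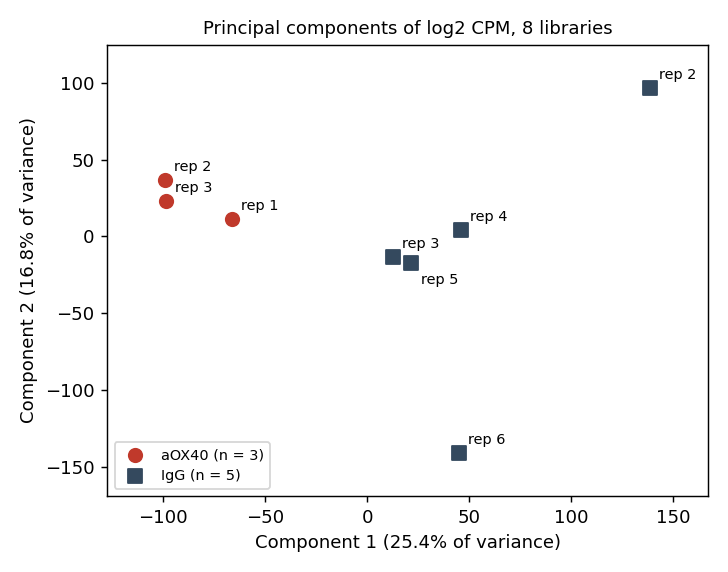
Each point is a library, placed by its first principal component of log2 CPM (horizontal axis, 25.4% of the variance) and its second (vertical axis, 16.8%), with circles for the 3 aOX40 libraries and squares for the 5 IgG libraries. The aOX40 libraries lie at -98.8 to -66.4 on the first component, and the IgG libraries lie at 12.7 to 139.

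Neutrophils of the aOX40 and IgG groups differed in many genes, in both directions. The largest increase among named genes was in Saa3, an acute-phase serum amyloid gene, at 99.4 ± 64.7 CPM in aOX40 (SD, n = 3) against 5.45 ± 5.41 CPM in IgG (SD, n = 5), a log2 fold change of 4.14 (SE 0.61, adjusted p = 0.00996, edgeR). Nqo1, a quinone reductase, rose from 1.80 ± 1.82 to 26.8 ± 12.5 CPM (log2 fold change 3.86, SE 0.58), and Cfb, complement factor B, rose from 2.18 ± 1.23 to 18.5 ± 3.89 CPM (3.08, SE 0.44). Uba2, a subunit of the SUMO-activating enzyme, rose by 3.21 on the log2 scale, Ptges, a prostaglandin E synthase, by 2.81, the proton channel Hvcn1 by 2.81, Filip1l by 2.67 and the betaine transporter Slc6a12 by 2.59. Among genes that met the naming rule for the largest changes, the largest decreases were in Aspg, an asparaginase (3.05 ± 0.52 against 33.6 ± 14.9 CPM, log2 fold change -3.46, SE 0.44), and Aopep, an aminopeptidase (4.39 ± 1.71 against 47.1 ± 38.6 CPM, -3.43, SE 0.65). Tex2 (log2 fold change -3.18), the zinc finger gene Plagl1 (-3.17), the collagen gene Col1a1 (-3.09), the integrin gene Itgb3 (-3.06) and the deubiquitinase gene Usp36 (-3.02) also fell. Col1a1 is on the fibroblast and pericyte marker list, so its reads need not come from neutrophils. It ran from 3.42 to 32.4 CPM between IgG libraries and was not called in 11 of 22 alternative analyses. That list's markers summed to 24.7 ± 4.54 CPM in aOX40 and 30.3 ± 12.1 CPM in IgG (exact permutation p = 0.607). Proscos fell by 3.20, but it lies antisense to Plpbp, which also fell (log2 fold change -1.80), and their reads may not be told apart here.

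Of 13278 genes tested with edgeR's quasi-likelihood test, 750 had an adjusted p below 0.05, with 351 higher and 399 lower in aOX40, and 673 of them had a log2 fold change of at least 1 in size (329 higher, 344 lower). In 730 of the 750 the 2 groups did not overlap; of all tested genes 2120 showed no overlap, where chance gives 3.57%. The spread between libraries was wide, with a biological coefficient of variation of 84.7%. The number of genes past the threshold depended on single libraries. Without aOX40 replicate 2 edgeR called 0 genes (2230 at an unadjusted p below 0.05), and without aOX40 replicate 3 it called 59. Of the 56 called genes that the naming rule took, 0 and 11 were called again in these 2 analyses. Their fold changes stayed on the same side of 0 in each of the 22 alternative analyses where they were tested, with a log2 fold change of 3.53 to 4.97 for Saa3, -3.89 to -3.15 for Aspg and -2.29 to -1.80 for Oas2. Where the groups did not overlap, leaving out 1 library could hardly turn the side, so this says little about single libraries. Without IgG replicate 3 edgeR called 497 genes and without IgG replicate 6 it called 475. Several genes named below lost their call at least as often as Col1a1. Of 22 alternative analyses, Cxcl3, Mmp8, Mmp9, Pdia3 and mt-Cytb were not called in 14, and mt-Nd4 and Atp5a1 in 13. Cd177 and Dnajb9 were not called in 12 and Cox5b in 11. The adjusted p of these genes lay between 0.0414 and 0.0490 (edgeR). Scaling by total counts alone shifted the median log2 fold change of all genes by 0.30 and gave 874 higher and 246 lower genes, so that 78.0% of calls were higher against 46.8%. The share was 32.4% with a correction for transcript length and 36.2% with a correction for GC content.

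**Figure D2:**
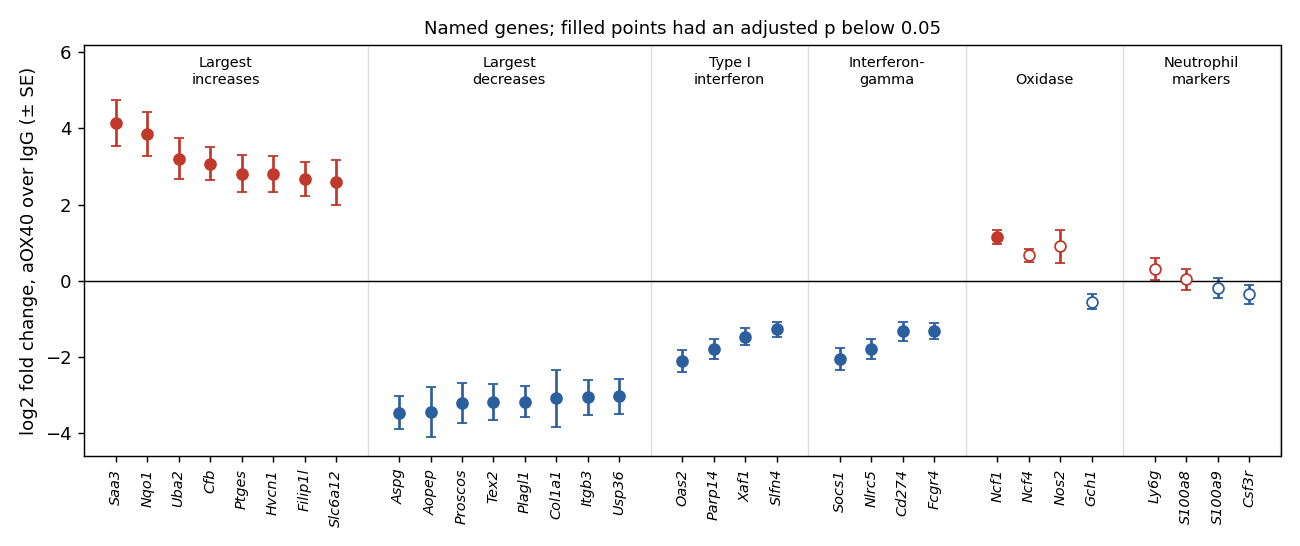
Each point is a gene's log2 fold change of aOX40 (n = 3) over IgG (n = 5) on the vertical axis, with bars of 1 SE and genes grouped along the horizontal axis. Filled points had an adjusted p below 0.05; the interferon genes shown lie between -2.10 and -1.27, and the neutrophil markers between -0.35 and 0.31 are all open.

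Interferon-induced genes were lower after aOX40. Of 32 measured members of the type I interferon list, 11 fell and 0 rose over all genes tested, and 22 fell when adjusted over the list alone. All 32 had a log2 fold change below 0, with a median of -1.09. Oas2, an antiviral oligoadenylate synthetase, stood at 26.6 ± 3.49 CPM in aOX40 and 114 ± 34.5 CPM in IgG (log2 fold change -2.10, SE 0.28). Parp14, an ADP-ribosyltransferase, fell by 1.79 on the log2 scale, Xaf1 by 1.46 and the schlafen gene Slfn4 by 1.27. Of 31 members of the interferon-gamma list, 7 fell and 0 rose, 11 fell when adjusted over the list alone, and the median was -0.88. Socs1, a feedback inhibitor of cytokine signalling, was at 253 ± 40.5 CPM in aOX40 and 1041 ± 361 CPM in IgG (-2.04, SE 0.29), and Nlrc5, a transactivator of MHC class I genes, fell by 1.79. Cd274, which encodes the checkpoint ligand PD-L1, was at 1455 ± 137 CPM against 3632 ± 1042 CPM (-1.32, SE 0.25, adjusted p = 0.0191), and the Fc receptor gene Fcgr4 fell by 1.31. With the preset correlation the camera adjusted p was 8.77e-18 for the type I list and 2.65e-11 for the interferon-gamma list, and with an estimated correlation the adjusted p was 0.298 for each. The preset correlation also called the type I list in 36 of the 56 splits of the libraries, with 4.99e-28 when IgG replicates 3, 4 and 6 were set against the rest, so its p alone does not tie the list to treatment. A list that follows RNA quality, the mitochondrial messenger RNAs, also differed between the groups (camera adjusted p = 1.43e-04, 0.553 with an estimated correlation), and its part in the interferon result was not tested. The mean log2 CPM of the type I list was 6.30 ± 0.14 in aOX40 and 7.41 ± 0.57 in IgG, lower in all 3 aOX40 libraries than in any IgG library (exact two-sided permutation p = 0.0357, 0.155 after adjustment over the lists).

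**Figure D3:**
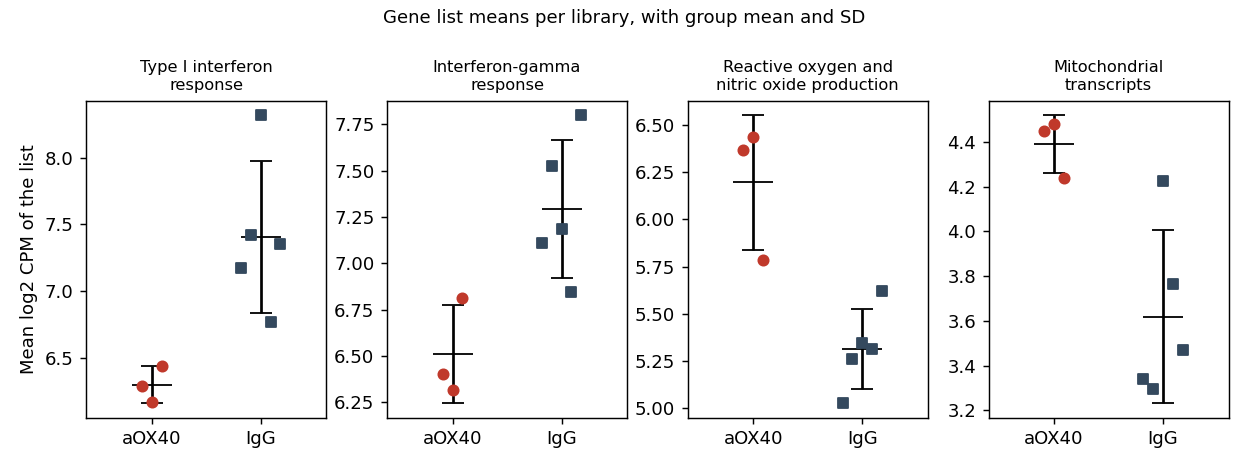
Each panel gives the mean log2 CPM (vertical axis) of the tested members of a gene list per library, for the 3 aOX40 libraries (circles) and the 5 IgG libraries (squares), with the group mean and 1 SD as bars; each vertical axis has its own range and does not start at 0. The type I interferon list lies at 6.17 to 6.44 in aOX40 and at 6.77 to 8.32 in IgG.

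The genes of reactive oxygen and nitric oxide production and the messenger RNAs of the mitochondrial genome were higher after aOX40 as lists. In the list of reactive oxygen and nitric oxide production, 2 of 12 members rose and 0 fell over all genes, while 5 rose and 1 fell when adjusted over the list alone, with a median of 0.74. Ncf1, an organizing subunit of the phagocyte oxidase, was at 321 ± 40.0 CPM in aOX40 and 145 ± 15.4 CPM in IgG (log2 fold change 1.14, SE 0.18). Hvcn1 was at 21.7 ± 7.50 against 3.14 ± 2.15 CPM. It overlaps Tctn1 on the other strand, which was near 1.41 and 1.53 CPM in the 2 groups. Ncf4, another oxidase subunit, had a log2 fold change of 0.67 (SE 0.18, adjusted p = 0.0559) and Gch1, which makes a cofactor of nitric oxide synthase, of -0.54 (SE 0.19, adjusted p = 0.110), and neither passed. Nos2, the inducible nitric oxide synthase, did not pass either, at 164 ± 59.4 CPM against 87.3 ± 48.1 CPM (0.91, SE 0.43, adjusted p = 0.223). The mitochondrial list is 1 of the 3 lists fixed beforehand as following RNA quality or tissue handling, so its change need not be one of cell state. All 13 mitochondrial messenger RNAs were above 0, with a median of 0.73; mt-Nd4 rose by 0.79 on the log2 scale and mt-Cytb by 0.95, and 4 rose when adjusted over the list alone. With 1 library left out, 0 of the 13 passed in 7 of the 8 analyses, while the list median stayed between 0.64 and 0.89. Mitochondrial messenger RNAs made up 0.126 ± 0.026% of counts in aOX40 and 0.0642 ± 0.0115% in IgG (exact permutation p = 0.0357). Mitochondrial ribosomal RNA was not higher, at 0.0788 ± 0.0271% against 0.0835 ± 0.0141% (exact permutation p = 0.714), and all mitochondrial transcripts together made up 0.205 ± 0.043% against 0.148 ± 0.020% (exact permutation p = 0.0714). The camera adjusted p was 0.00662 for the oxygen list and 1.43e-04 for the mitochondrial list, and with an estimated correlation the adjusted p was 0.298 and 0.553.

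The IL-4 and STAT6 list had 2 of 8 members lower, and also 2 when adjusted over the list alone. They were Cish, a cytokine-induced feedback inhibitor (66.2 ± 12.2 against 169 ± 32.9 CPM, log2 fold change -1.35, SE 0.23), and Pdcd1lg2, which encodes the checkpoint ligand PD-L2 (38.9 ± 8.85 against 113 ± 29.8 CPM, -1.55, SE 0.28). Its camera adjusted p was 0.0485 and its adjusted p with an estimated correlation was 0.298. The call was lost without aOX40 replicate 3 (0.135), IgG replicate 5 (0.0677) or IgG replicate 6 (0.0515).

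Other groups of immune genes moved in both directions. In the NF-kB list, the neutrophil chemokine gene Cxcl1 rose (68.7 ± 41.0 against 12.2 ± 5.93 CPM, log2 fold change 2.48), while the chemokine gene Cxcl3 fell by 1.03 and Zfp36, a destabilizer of cytokine messenger RNAs, fell by 1.21. The other 27 of 30 members did not pass. Scaling by total counts alone gave 4 higher and 1 lower members in this list, and Cxcl3 was no longer called. Members of the Fc receptor and phagocytosis list also went both ways, and those that fell included Fcgr4, Fcgr3 and the beta-glucan receptor gene Clec7a, the last from 3585 ± 658 to 1548 ± 165 CPM (-1.21). Among granule proteins the collagenase gene Mmp8 rose (1093 ± 543 against 479 ± 111 CPM, 1.19), as did Prtn3, at 1.22 ± 0.28 against 0.096 ± 0.15 CPM. Prtn3 overlaps Plppr3 on the other strand and was not called in 11 of 20 alternative analyses. Of the adhesion receptors, the integrin gene Itgb2 rose by 1.07 and Cd177, a neutrophil surface glycoprotein, by 1.34. In the suppressive myeloid list Ptges rose and Cd274 and the galectin gene Lgals9 fell, by 1.32 and 1.18. In the MHC class I list H2-T23 fell by 0.78 and the chaperone gene Pdia3 rose by 0.78, and in the MHC class II list 0 of 12 members passed in edgeR. The balance of calls in the MHC class I list depended on the scaling. Total counts alone gave 2 higher and 0 lower, without H2-T23, and upper quartile factors gave 0 higher and 2 lower, without Pdia3. The mean log2 CPM of the MHC class II list was 3.81 ± 0.05 in aOX40 and 3.28 ± 0.35 in IgG, without overlap (exact permutation p = 0.0357, 0.155 after adjustment over the lists). The camera adjusted p was 0.326 for the NF-kB list, 0.154 for Fc receptors, 0.230 for granule proteins, 0.727 for adhesion receptors, 0.170 for the suppressive list, 0.370 for MHC class I and 0.727 for MHC class II. Fry called the Fc receptor and suppressive lists lower (adjusted p = 0.0385 and 0.0491) and none of the others named here. With an estimated correlation camera gave 0.371 and 0.372 for these 2 lists. Single libraries changed some of these: the NF-kB list had 0.00791 and a median of 0.60 without aOX40 replicate 2, and a median of 0.03 against 0.46 without aOX40 replicate 3, where the granule list had 0.0364. With the length correction the Fc receptor, suppressive and MHC class I lists had 0.0259, 0.0266 and 0.0233. When adjusted over the list alone, 5 rose and 4 fell in the NF-kB list. Likewise 3 rose and 1 fell among granule proteins, 4 rose and 2 fell among adhesion receptors, and 2 rose and 2 fell in each of the suppressive and MHC class I lists.

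Genes of stress and metabolism also changed, within lists that did not pass as a whole in the analysis reported here. Hk2, a hexokinase, fell from 114 ± 18.9 to 27.6 ± 14.4 CPM (log2 fold change -2.06, SE 0.32) and was the only member called of 28 in the hypoxia and glycolysis list (camera adjusted p = 0.156). That list passed with the replicate block (0.000502), the length and GC corrections (0.0233 and 0.0406) and without IgG replicate 6 (0.0404). With the block, only the libraries numbered 2 and 3 bear on the comparison. These calls used the preset correlation. With an estimated correlation (0.322) and all libraries its camera adjusted p was 0.804. Ddit3, a stress-induced transcription factor, fell by 1.59 and the co-chaperone gene Dnajb9 by 1.00, in an unfolded protein list whose other 20 of 22 members did not pass (0.514). The stress genes Atf3, Hsp90aa1 and Hspa1b fell by 1.42, 1.29 and 1.63. Hspa1b has a near copy in Hspa1a and Hsp90aa1 in 2 unnamed models, so reads could be split between them. They belong to the immediate early and heat shock list, where 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.241, but 0.0266 with the length correction and 0.0245 without aOX40 replicate 3). Of the apoptosis list, Bid, a death agonist, rose by 1.03 and Bcl2l1, a survival gene, fell by 0.93, with 24 of 26 members not passing (0.891). In oxidative phosphorylation, Atp5a1 rose by 0.88 while Cycs fell by 1.15 and Cox5b by 1.02 (0.582), and in the cell cycle list Mcm7 rose between low levels, at 4.83 ± 2.89 against 0.53 ± 0.43 CPM (0.370). Mcm7 has a near copy in an unnamed model and overlaps 2 other genes of the table, so its reads could be shared too. Scaling by total counts alone gave 4 higher and 0 lower members in oxidative phosphorylation, where edgeR no longer called Cycs and Cox5b, and 3 higher and 1 lower in the unfolded protein list, so the balance of calls in these lists depended on the scaling. When adjusted over the list alone, 1 fell in the hypoxia list, 2 rose and 3 fell in the unfolded protein list, and 1 rose and 3 fell in the apoptosis list. Likewise 1 rose and 2 fell in oxidative phosphorylation, and 1 rose in the cell cycle list.

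Both groups carried high levels of neutrophil markers. The 27 neutrophil markers summed to 39715 ± 4226 CPM in aOX40 (SD, n = 3) and 39782 ± 4700 CPM in IgG (SD, n = 5; exact two-sided permutation p = 1). S100a8 was at 5773 ± 2032 against 5596 ± 1504 CPM, S100a9 at 7088 ± 2469 against 8066 ± 1717 CPM, Ly6g at 111 ± 31.2 against 89.5 ± 28.5 CPM and the G-CSF receptor gene Csf3r at 690 ± 200 against 880 ± 205 CPM, and none of these passed the test. Within this list Slfn4 fell, and Cd177 and the gelatinase gene Mmp9 rose (983 ± 444 against 405 ± 118 CPM). Markers of other cells were far lower. Macrophage and monocyte markers summed to 723 ± 105 against 650 ± 232 CPM, T cell markers to 13.7 ± 8.61 against 10.2 ± 3.91 and melanoma markers to 16.6 ± 6.33 against 24.2 ± 7.11 CPM. Dendritic cell markers summed to 32.1 ± 6.52 against 50.9 ± 11.9 CPM, with an exact permutation p of 0.0357, not adjusted over the lists. Most of that sum was Itgax and Bst2, and Bst2 is also on the type I interferon list. The mean log2 CPM of the tested dendritic cell markers overlapped between the groups (exact permutation p = 0.321). The macrophage and monocyte sum was mostly Ly6c2 and Gpnmb, at means of 471 and 118 CPM over all libraries, so it says little of the other markers. Of these, Adgre1 rose (21.6 ± 6.37 against 6.12 ± 2.62 CPM, log2 fold change 1.81). Csf1r was at 51.2 ± 21.2 against 17.5 ± 8.26 CPM and did not pass (adjusted p = 0.0546, edgeR). Of 13 tested members of the list, 9 were above 0 and 4 below. Their mean log2 CPM was 1.98 ± 0.23 in aOX40 and 1.15 ± 0.62 in IgG (exact permutation p = 0.107). Erythroid markers summed to 366 ± 431 against 201 ± 223 CPM and varied from 8.17 to 864 CPM between libraries. Arg1 was at 4.76 ± 4.74 against 4.06 ± 2.21 CPM, Tnfrsf4 at 0.063 ± 0.109 against 0.37 ± 0.49 CPM, C1qa at 0.61 ± 0.16 against 0.44 ± 0.49 CPM and Pmel, a melanocyte gene, at 0.94 ± 1.25 against 0.75 ± 1.12 CPM, and none of these passed.

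On GRCm38, also called mm10, Saa3 lies on chromosome 7 from 46711998 to 46715700, Nqo1 on chromosome 8 from 107388225 to 107403206, Cfb on chromosome 17 from 34856374 to 34862518 and Aspg on chromosome 12 from 112106679 to 112127559. Cd274 lies on chromosome 19 from 29367455 to 29388095, on the same chromosome as Pdcd1lg2 at 29410919 to 29471161. Oas2 lies on chromosome 5 from 120730333 to 120749853, Socs1 on chromosome 16 from 10782240 to 10785536, Ncf1 on chromosome 5 from 134220053 to 134229625 and Nos2 on chromosome 11 from 78920787 to 78960254. These 10 are annotated as protein coding, and their values are sums over the whole gene.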

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

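In the 5 IgG libraries, 101 sets of values were searched for a library far from the other 4, and 6 were found where chance gives about 1 in 20, or 5.05. The gap to the nearest library, as a share of the whole range, was 0.714 for the mean of the cell cycle list (IgG replicate 2 lowest), 0.730 for the mean of the dendritic cell list (IgG replicate 4 lowest), 0.714 for Cfb (IgG replicate 4 at 0.074 CPM), 0.769 for Aopep (IgG replicate 2 at 114 CPM, the next at 42.4), 0.741 for Csf3r (IgG replicate 4 at 1237 CPM) and 0.802 for Pmel (IgG replicate 4 at 2.72 CPM). The 3 aOX40 libraries are too few for such a search.

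The tests with GC content and fry, the restriction to well counted genes, the list means with 1 library left out and the other splits for the gene lists were chosen after the result was seen. The first pattern is the count of 750 changed genes. Of the 56 splits of the 8 libraries into 3 and 5, only the real split gave that many (1 of 56, and the highest of the others gave 0). This argues against a chance division of these libraries, but only weakly. The other splits mix the groups, which widens the spread within each side. The real grouping also gave 0 genes without aOX40 replicate 2. With a correction for transcript length 73.9% of the called genes stayed past the threshold, so length is not the whole cause. Of the called genes 78.7% had at least 10 counts in all 8 libraries. They included 219 of the 351 higher genes (62.4%) and 371 of the 399 lower genes (93.0%), against 66.6% of all tested genes. Transcripts missed in the shallower IgG libraries could give such a gap between higher and lower genes. A test of well counted genes alone, with fewer genes to adjust over, called 384 higher. Missed transcripts are thus not the whole cause of the higher genes, but a part is not excluded. Depth differed with group, and treatment is a candidate explanation that this design does not separate from it.

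The second pattern is the lower interferon lists. The median of the type I list was -1.26 with the length correction and -1.16 with the GC correction, and fry, which allows for correlation between genes, kept the list in both (adjusted p = 0.0267 and 0.0399), which argues against these as the whole cause. Fry lost the type I list with scaling by total counts (adjusted p = 0.0573), without the filter (0.0558) and with the replicate block (0.212). It also lost the interferon-gamma list with total counts (0.0598) and with the block (0.252). The block leaves only the libraries numbered 2 and 3 to compare, so a call lost with it says little. With 1 library left out the median stayed between -1.17 and -0.73 and the difference in list means was at least 2.04 SD. The groups did not overlap in this mean, so leaving out 1 library could change the size of the difference but not its sign. No single library made up the whole size, but fry with fewer libraries passed in only 2 of the 8 cases. Camera also lost the list with an estimated correlation (0.298). Only the real split, 1 of 56, gave a median as far from 0 (the next was 0.93 in size), but the list is 1 of 26 and the exact permutation p of 0.0357 became 0.155 after adjustment over the lists. The prediction had not allowed for the number of lists, so a state that varies between animals whatever the treatment cannot be told apart from an effect of treatment, and RNA quality, which was not tested, stays open too.

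The third pattern is the higher oxygen list and mitochondrial messenger RNAs. With the length correction the larger camera adjusted p of the 2 lists was 0.0233 and the larger fry adjusted p 0.0323, so transcript length is not the whole cause. With any library left out the camera adjusted p was at most 0.0291 (without IgG replicate 3). The medians stayed between 0.62 and 0.74 and between 0.64 and 0.89, and the list means differed by at least 2.86 and 2.06 SD. The groups did not overlap in either mean, so leaving out 1 library could change the size of the difference but not its sign. No single library made up the whole size, but fry passed the mitochondrial list in only 1 of the 8 cases (the oxygen list in all 8). Camera lost both lists with an estimated correlation (0.298 and 0.553), and with the preset correlation 24 of the 56 splits called as many lists as the real split (5, the highest 11), so the number of called lists could come from chance. Depth differed between the groups in the same direction, and the mitochondrial list was fixed to follow RNA quality (the other 2 such lists had a camera adjusted p of 0.148 and 0.241), so depth and RNA quality both stay open. Of those 2, the ribosomal protein list passed as lower without aOX40 replicate 1 (0.0158), and the heat shock list passed in the settings given above.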

How the results depend on the processing

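The corrections for transcript length and GC content, fry beside the other settings and the restriction to genes with 10 counts in all libraries were chosen after the data were seen. In none of these 22 settings did a called gene turn direction, which 1 library left out could hardly cause where the groups did not overlap. Of 56 called genes that the naming rule took, between 0 (without aOX40 replicate 2, and with the block) and 55 (DESeq2) were called again. Changed genes numbered 452 (194 higher, 258 lower) without the filter, 320 (109, 211) with the older edgeR setting, 1457 (951 lower) with DESeq2 and 1305 (622, 683) with voom quality weights. Scaling by total counts gave 874 higher and 246 lower, and the length correction 228 higher. With 1 library left out, the count ran from 0 to 589, the higher genes from 0 to 263 and the lower from 0 to 326. The replicate numbers 2 and 3 occur in both groups, and the labels do not say whether they pair them. Deviations from the group means correlated at 0.022 and 0.047 between libraries of the same number. Each was the highest for its aOX40 library, but values this small cannot tell whether the numbers pair the groups. With the replicate block edgeR called 0 genes, 0 higher and 0 lower (2594 at an unadjusted p below 0.05), and the IL-4 list had 0.242. With the block only the libraries numbered 2 and 3 bear on the comparison, and almost no degrees of freedom are left to measure the spread. Calls lost or gained with it therefore say little. The count of lists was 11 with the length correction and 0 with an estimated correlation, where the adjusted p was 0.298 for the type I interferon, interferon-gamma, oxygen and IL-4 lists and 0.553 for the mitochondrial list; fry called 7 lists. The IL-4 list also had an adjusted p of 0.0502 with DESeq2 size factors, 0.0525 with upper quartile factors, 0.0820 with the stricter filter, 0.118 with 10 counts in all libraries and 0.0201 to 0.135 with 1 library left out. On total-count CPM the log2 ratio of neutrophil markers was 0.30 against -0.0024. The cause of these differences was not tested. In simulated data 16% of genes changed 2-fold were recovered, among genes with a mean of at least 10 CPM, so small changes are often missed at this spread.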

Other observations

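Further genes that changed were chosen after their values were seen. The receptor beta chain genes Csf2rb and Csf2rb2 fell, Csf2rb from 1294 ± 248 to 366 ± 71.6 CPM and Csf2rb2 from 235 ± 94.7 to 75.3 ± 26.1 CPM. So did the kinase gene Pim1 (log2 fold change -1.13). Csf2rb and Csf2rb2 were not searched for near copies, so reads could be shared between them. The long noncoding RNA Malat1 fell from 8305 ± 2537 to 2948 ± 971 CPM. Irak3, which restrains Toll-like receptor signalling, and the lectin-like gene Chil1 rose, with log2 fold changes of 2.10 and 1.25.

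After Nqo1, Prdx1, Pgd and Blvrb were seen to rise (Prdx1 from 30.3 ± 12.0 to 175 ± 14.1 CPM, Pgd from 103 ± 26.1 to 291 ± 43.9 CPM), a list of 16 other targets of NRF2, the transcription factor of the oxidative stress response, was written down before their values were seen. Of 15 tested, 12 had a log2 fold change above 0 and the median was 0.70. Gclm, Srxn1 and G6pdx rose over all genes tested (1.29, 1.33 and 1.23), and 6 rose and 1 fell when adjusted over the list alone. Osgin1, Txn1 and Hmox1 had values below 0 (-0.80, -0.46 and -0.21). The camera p was 6.74e-04 with the preset correlation and 0.0174 with an estimated correlation, and the exact permutation p of the list mean was 0.0357. A shared NRF2 program is therefore a hypothesis that these values are consistent with, although 3 members went the other way.

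A lysosomal program was tested in the same way after Psap, Ctsc, Lipa, Creg1, Fuca1, Neu1, M6pr and Ggh were seen to rise. The 29 other lysosomal genes had a median log2 fold change of 0.26, with 20 above 0, a camera p of 0.104 and an exact permutation p of 0.179, so these data do not decide it. A difference in circadian phase was tested after Ciart and Per1 were seen to fall (-2.56 and -1.45). The 6 other genes of the Dbp and Per arm that could be tested had a median of -0.51, 4 below 0, and an exact permutation p of 0.393, and most lay under 5 CPM, so this too was not decided.

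Reads appeared to be divided between near-identical genes. Ftl1 and its pseudogene Ftl1-ps1 had similar shares in each library, from 1.17% and 1.14% of counts in aOX40 replicate 3 to 2.30% and 2.17% in aOX40 replicate 1; they differed most in IgG replicate 4, at 1.80% and 1.47%. Listed cytosolic ribosomal protein genes together took only 0.0674% to 0.110% of counts.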
